A study of Mus musculus with 21 samples.

How the data were processed

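RNA was sequenced from immortalized mouse embryonic fibroblasts (MEFs) of lines that stably express LacZ or V5-tagged GCN5, after transfection for 2 days with 10 nM control siRNA (siControl) or siRNA against Hsf1 (siHsf1). The 12 RNA libraries form 4 groups of 3, called triplicates in the labels, which do not say whether these were separate cultures; p-values therefore measure the spread between libraries as labelled. Binding of c-MYC was mapped by CUT&RUN, in which an antibody directs a nuclease to cut the DNA around a bound protein, in MEFs with Hsf1 present (WT) or deleted with 4-hydroxytamoxifen (CKO). The 5 CUT&RUN libraries are 2 per genotype and 1 with IgG on mixed cells. ERCC spike-in RNA was added to the RNA samples and E. coli DNA to the CUT&RUN samples.

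The authors deposited a table of counts per gene, in whole numbers, for 41608 genes with 92 ERCC transcripts in the same table. A second table deposited by the authors gives FPKM, whose library denominators lie between 0.984 and 1.05 times the column sums of the counts. FPKM values were used for this check alone. The c-MYC peaks are 1 list per genotype, and each peak carries the signal made by the authors, which is the coverage summed over the peak. Each also carries a score made by the authors, the maximal coverage in the peak, and both are per-peak values of the authors rather than recomputed ones. Per the labels, reads were mapped with HISAT2 for RNA and Bowtie2 for CUT&RUN on GRCm38 or mm10, with DESeq2 and SEACR for later steps. The counting program and the versions are not given in the sources used here. The peak lists are named as SEACR stringent calls against IgG and were assigned to genotypes by those names. Whether the 2 replicates of a genotype were pooled is not stated, so nothing on peaks has a replicate error.

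Gene positions and types came from the GRCm38.p6 annotation, which matched 40306 genes by identifier. Total gene counts per library ran from 3.69 to 8.16 M (mega) counts, with 7.22 to 8.16 M in the LacZ line and 3.69 to 4.27 M in the GCN5 line, so that depth and line coincide. A count of 0 allows up to 0.368 to 0.812 CPM (counts per megacount of the library), from 3 counts of a library's total. Such floors, and the Wilson intervals of 95% given for shares, cover counting error only.

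Differential expression was tested in R 4.3.3 with edgeR 4.0.16, by robust quasi-likelihood tests on a model of 4 group means with 8 residual degrees of freedom. The filter filterByExpr, with a minimum count of 10, left 12187 genes. Tests were two-sided, and adjusted p-values are Benjamini-Hochberg values, with calls at an adjusted p under 0.05. Fold changes carry the standard error (SE), group means the standard deviation (SD). Libraries were scaled by the summed counts of the 23 ERCC transcripts of subgroup B, which have the same amount in both mixes, because the series names ERCC spike-in for its expression libraries. The subgroup B sums were 7460 to 29584 counts, over the set minimum of 1000. The spike-in share of libraries of 1 group varied, with a common biological coefficient of variation of 0.274 after this scaling and 0.089 after TMM scaling. Results with TMM scaling stand beside the spike-in results for this reason, a choice made after the data were seen. TMM assumes that most genes do not change, and spike-in scaling does not.

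The 28 gene lists and 7 lists of cell type markers were written from general knowledge before the data were examined, as were the comparisons, the spike-in scaling, the filters, the rule for named genes and most alternatives. The ERCC subgroups, 4 in number, were also listed from memory. Of 892 list members, 890 are in the count table, and Utp4 and Selenos are not. Lists were tested with camera of limma 3.58.1 with its preset correlation of 0.01, on log2 CPM with a prior count of 2, adjusted over the lists of a comparison; the same test was run with a correlation estimated from the residuals. With spike-in scaling this estimate includes the spike-in error that all genes of a library share, which raises it for any list. A high adjusted p from it therefore does not show that a list is unchanged. A list's relative median is the median log2 fold change of its members minus that of all tested genes. Spike-in scaling moved the all-gene median to -0.36 for siHsf1 in LacZ, -0.03 for siHsf1 in GCN5, -0.38 for the line under siControl, -0.03 for the line under siHsf1 and 0.34 for the interaction.

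Hsf1, Kat2a (GCN5) and Myc are given in every library. In each comparison the rule names the 10 largest positive and 10 largest negative fold changes among called protein-coding genes with a mean log2 CPM of at least 2. It also asks that every library of 1 group lie above every library of the other, which chance meets for 10% of genes, and this last condition was not used for the interaction. From each list that passes, up to 4 members with the smallest p are named, and up to 2 of a list that does not. Some genes that the rule takes are not reported here.

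Peaks were read in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. CKO peaks counted as shared when they overlapped a WT peak by at least 1 bp, and gene starts as bound when a peak lay within 1000 bp. The background for both was the same count after shifting the peaks along the chromosomes. Genes with the 1000 highest summed start signals in WT, those bound in WT alone and those bound in both were tested as sets under siHsf1. For each genotype the 10 genes with the highest start signal are named, with classical MYC targets and chaperones.

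Alternatives were TMM, RLE, total counts and all ERCC transcripts for scaling, no filter or a minimum count of 50, DESeq2 1.42.0, each pair of groups fitted on its own, a replicate block, each library left out, and other peak thresholds, overlaps and windows. Counts of the 12 libraries were also simulated from gene means over all groups, with changes placed in the siHsf1 LacZ libraries. There edgeR with TMM called 76 of 99 genes changed 2-fold and 97 of 101 changed 4-fold, with 0.127% of unchanged genes called. With spike-in scaling it called 38 of 111 and 83 of 89, with 0.076% of unchanged genes called. The simulated genes did not follow the spike-in shares, so all variation of these shares acted as error. The series also holds 4 libraries of a Myc knockdown set, for which no column was found in the tables, and they are not analysed here. The search for E-boxes in the peaks was not run, as no genome sequence was at hand. Figures were drawn with matplotlib 3.10.9.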

Results

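The series asks how HSF1, the transcription factor that drives the heat-shock response, affects transcription by c-MYC, a growth-promoting transcription factor, and includes a line made to express GCN5 (gene Kat2a), the histone acetyltransferase of the SAGA and ATAC complexes. It holds 21 samples. RNA was measured in 3 libraries each of siControl LacZ, siHsf1 LacZ, siControl GCN5 and siHsf1 GCN5 MEFs. Total gene counts averaged 7.81 ± 0.43 M (mega; SD, n = 3) in siControl LacZ, 7.81 ± 0.51 M in siHsf1 LacZ, 3.73 ± 0.03 M in siControl GCN5 and 4.13 ± 0.16 M in siHsf1 GCN5 libraries. In each library 11094 to 12422 genes had at least 10 counts. Counts of libraries of 1 group correlated at r = 0.977 to 0.985 across genes, which are not independent replicates. ERCC transcripts took 0.711% to 1.65% of the counts. The share of ERCC subgroup B was 1.35-fold as high in siHsf1 as in siControl LacZ libraries (exact permutation test, two-sided, p = 0.4, where 3 against 3 libraries can give no p under 0.1). It was 1.03-fold as high in siHsf1 as in siControl GCN5 libraries (exact permutation p = 1). In replicates 1, 2 and 3 the share was 0.143%, 0.242% and 0.192% in siControl LacZ and 0.179%, 0.362% and 0.251% in siHsf1 LacZ. These tests took the libraries as unpaired, so spread that follows the replicate number counted as error. Their p-values therefore do not show that the shares were equal. The labels name different ERCC mixes for siControl and siHsf1, yet the ratio of subgroup A to subgroup B counts was 1.43 to 1.47 in all 4 groups. Subgroup B is the part of the mixes that such a difference leaves alone. The c-MYC peaks comprise 1 list for Hsf1 WT and 1 for Hsf1 CKO MEFs, with no replicates.

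Hsf1 transcripts were lower in each siHsf1 library than in each siControl library of the same line, and Kat2a and Myc transcripts were lower in each siHsf1 library of the LacZ line alone. Hsf1 (gene 15499; GRCm38 chromosome 15, 76477367 to 76500982) stood at 128, 128 and 134 CPM (TMM-scaled) in siControl LacZ replicates 1 to 3 and at 57.6, 55.4 and 47.8 CPM in siHsf1 LacZ replicates 1 to 3. In the GCN5 line Hsf1 stood at 137, 121 and 138 CPM with siControl and at 67.9, 74.5 and 73 CPM with siHsf1. Kat2a (gene 14534; chromosome 11, 100704746 to 100712478) stood at 215, 215 and 220 CPM in siControl LacZ, 125, 117 and 130 CPM in siHsf1 LacZ, 262, 233 and 245 CPM in siControl GCN5 and 247, 252 and 244 CPM in siHsf1 GCN5 libraries. The labels do not give the species of the V5-GCN5 construct, so Kat2a counts do not test that label, and the line is called GCN5 as labelled. Myc (gene 17869; chromosome 15, 61985341 to 61990361) stood at 130, 142 and 147 CPM in siControl LacZ, 99.4, 89.4 and 88.1 CPM in siHsf1 LacZ, 129, 108 and 125 CPM in siControl GCN5 and 158, 144 and 139 CPM in siHsf1 GCN5 libraries.

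**Figure D1:**
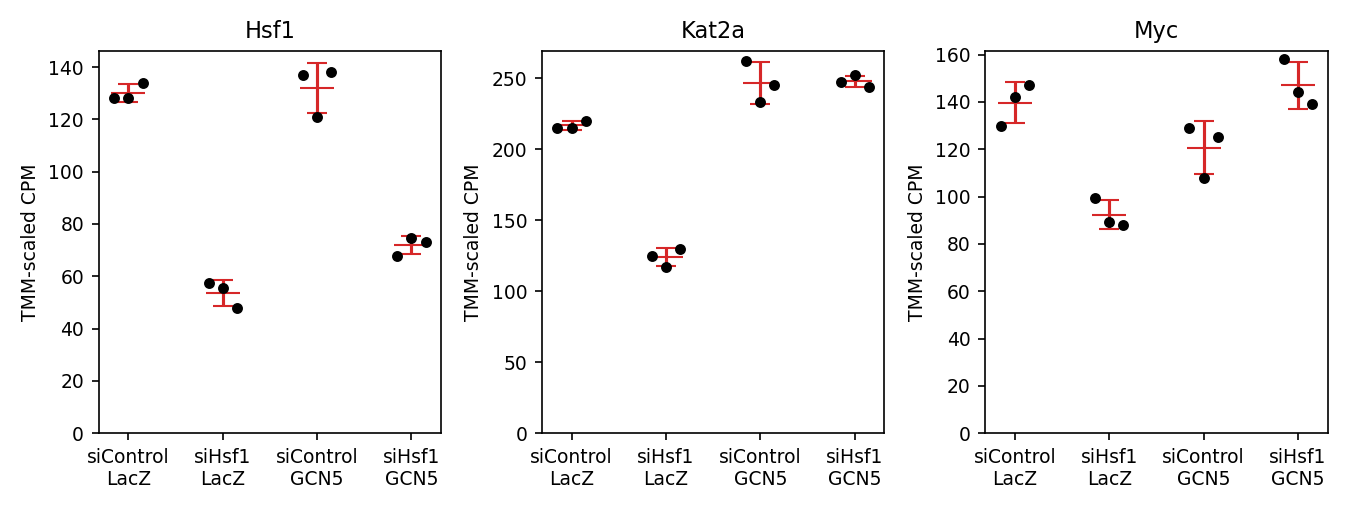
TMM-scaled CPM (y axes) of Hsf1, Kat2a and Myc in the 4 groups (x axes), with black points for libraries and red marks for the mean ± SD (n = 3). Kat2a averaged 217 CPM in siControl and 124 CPM in siHsf1 LacZ libraries, against 247 and 248 CPM in the GCN5 line.

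Knockdown of Hsf1 in the LacZ line, which asks what loss of HSF1 does to expression where GCN5 is not added, went with higher type I interferon response genes and, by camera with its preset correlation, with lower ribosomal protein, MYC target, chaperone and mitosis lists relative to all genes. When the correlation was estimated, the camera adjusted p was 0.018 for the interferon list and 0.73 for each of the lower lists. With an estimated correlation and TMM scaling it was 0.1 for ribosomal proteins and under 0.05 for the MYC target, heat-shock chaperone and mitosis lists. With spike-in scaling the estimate holds the error shared by all genes of a library, so 0.73 does not show that a list is unchanged. Ifit3, an interferon-induced antiviral protein (chromosome 19, 34583142 to 34588982), rose 11.7-fold from 7.09 ± 2.25 to 81.8 ± 16.1 spike-scaled CPM (SD, n = 3 per group; log2 fold change 3.54 ± 0.36 SE, edgeR adjusted p = 1.3e-18). Hspd1, the mitochondrial chaperonin HSP60, fell (log2 fold change -1.68 ± 0.32 SE, edgeR adjusted p = 4.9e-05), as did Hsp90aa1, an HSP90 isoform (log2 fold change -1.29 ± 0.32 SE, edgeR adjusted p = 0.0035). Hsf1 itself fell to 0.319-fold (log2 fold change -1.65 ± 0.33 SE, edgeR adjusted p = 0.00012), Kat2a to 0.445-fold (-1.17 ± 0.32 SE, edgeR adjusted p = 0.011) and Myc to 0.52-fold (-0.94 ± 0.32 SE, edgeR adjusted p = 0.049). With TMM scaling Kat2a changed by -0.80 ± 0.06 (SE, edgeR adjusted p = 1.7e-10) and Myc by -0.60 ± 0.08 (SE, edgeR adjusted p = 7.2e-07).

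Among the 10 genes with the largest increases that the rule names, Ifi44 rose 8.93-fold and Usp18, which removes the interferon-induced ubiquitin-like protein ISG15, rose 8.21-fold. Irf7, a transcription factor that amplifies interferon production, rose 5.43-fold from 32.8 ± 6.96 to 178 ± 41.2 spike-scaled CPM (SD, n = 3 per group; edgeR adjusted p = 5e-10). Log2 fold changes (± SE) of the others were 3.03 ± 0.37 for Trim30a, 2.80 ± 0.34 for Xaf1, 2.46 ± 0.36 for Mmp13, a collagenase, 2.39 ± 0.36 for Oas3, an antiviral RNA sensor, and 2.23 ± 0.38 for Sp100. Rad9a, a DNA damage checkpoint protein, had 3.00 ± 0.49, with uneven siHsf1 libraries (SD 7.19 CPM). Reep6, an endoplasmic reticulum protein (chromosome 10, 80330003 to 80336441), fell to 0.136-fold, from 16.2 ± 4.25 to 2.2 ± 0.292 spike-scaled CPM (SD, n = 3 per group; edgeR adjusted p = 2e-09). Eda2r, a p53-induced receptor, fell to 0.191-fold (log2 fold change -2.39 ± 0.36 SE, edgeR adjusted p = 3.8e-08). The other named decreases, in log2 fold change (± SE), were Ube2cbp (-2.16 ± 0.43), Dusp9, a MAP kinase phosphatase (-2.03 ± 0.38), Psrc1, a spindle protein (-2.02 ± 0.35), Ppl, periplakin (-1.99 ± 0.40), Timm8a1, a mitochondrial import protein (-1.83 ± 0.33), Fam212b (-1.80 ± 0.43) and Gna11, a G protein subunit (-1.74 ± 0.33). Srp54b, which has near-identical copies in the genome, had -2.57 ± 0.36 (SE) with uneven siControl libraries.

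Of 71 ribosomal protein genes, 57 fell, 14 did not pass and 67 fell when adjusted over the list alone (relative median -0.70, camera adjusted p = 5.2e-21), with Rps25 at log2 -1.48, Rpl12 at -1.43 and Rps23 at -1.39. Of 56 MYC hallmark V2 targets, 34 fell and 48 did when adjusted over the list alone (relative median -0.68, camera adjusted p = 2.9e-17), among them Rcl1 (-1.52) and Mybbp1a (-1.41), both of the nucleolus. Of 30 classical MYC targets, 15 fell and 24 did when adjusted over the list alone (relative median -0.62, camera adjusted p = 1.2e-09). They include Ncl, nucleolin (-1.50), Ccnd2, cyclin D2 (-1.37), Cad, the enzyme that starts pyrimidine synthesis (-1.35), and Pno1, a ribosome assembly factor (-1.61). Of 43 ribosome biogenesis genes, 21 fell and 30 did when adjusted over the list alone (relative median -0.55, camera adjusted p = 1.4e-10), with Dkc1, the pseudouridine synthase, at -1.59 and Fbl, fibrillarin, at -1.33. Of 28 nucleotide synthesis genes, 13 fell and 22 did when adjusted over the list alone (relative median -0.59, camera adjusted p = 1.1e-08), with Mthfd1 at -1.45 and Gart at -1.29. Of 39 translation factors, 12 fell and 27 did when adjusted over the list alone (relative median -0.41, camera adjusted p = 2.8e-06), with Eef1b2 at -1.23. With an estimated correlation each of these 6 lists had a camera adjusted p = 0.73. With TMM scaling and an estimated correlation the camera adjusted p was 0.0059 for the classical MYC and nucleotide lists, 0.011 for MYC V2, 0.012 for ribosome biogenesis, 0.041 for translation factors and 0.1 for ribosomal proteins.

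Of 27 heat-shock protein and chaperone genes, 13 fell, 14 did not pass and 20 fell when adjusted over the list alone (relative median -0.52, camera adjusted p = 3.2e-08), with Fkbp4, an HSP90 co-chaperone, at -1.40 and Hspb1, a small heat-shock protein, at -1.38. Of 13 subunits of the cytosolic chaperonin TRiC and of prefoldin, which together fold actin and tubulin, 8 fell and 10 did when adjusted over the list alone (relative median -0.67, camera adjusted p = 0.00013), with Cct3 at -1.27 and Cct6a at -1.13. Of 32 mitosis genes, 12 fell and 29 did when adjusted over the list alone (relative median -0.57, camera adjusted p = 2.7e-09), with the kinases Aurka at -1.21 and Aurkb at -1.10. Of 26 p53 targets, 8 fell and 15 did when adjusted over the list alone (relative median -0.42, camera adjusted p = 0.00017), among them Cdkn1a, the cell cycle inhibitor p21 (-1.71), and Ccng1 (-1.60). Of 20 NRF2 targets, 4 fell and 6 did when adjusted over the list alone (relative median -0.31, camera adjusted p = 0.008), with Gsta4 at -1.34 and Nqo1, a quinone reductase, at -1.10. Glycolysis genes had 0 of 22 called (13 lower when adjusted over the list alone; relative median -0.40, camera adjusted p = 0.0033). Aminoacyl-tRNA synthetases had 1 of 20 lower (10 when adjusted over the list alone; -0.32, camera adjusted p = 0.017), and that was Farsb. Proteasome subunits had 0 of 31 called (-0.29, camera adjusted p = 0.0017), cholesterol synthesis genes 1 of 23 lower (-0.22, camera adjusted p = 0.014), and mitochondrial respiration genes 0 of 47 called (-0.15, camera adjusted p = 0.045). With TMM scaling edgeR called 15 glycolysis genes, 22 proteasome genes and 13 respiration genes lower and 2 glycolysis genes higher. Under an estimated correlation the camera adjusted p was 0.73 for 9 of these 10 lists and 0.85 for mitochondrial respiration. With TMM scaling and an estimated correlation, the camera adjusted p was 0.012 for mitosis and for p53 targets, 0.016 for chaperones and 0.046 for cholesterol synthesis. It was 0.098 for TRiC and prefoldin, 0.065 for NRF2 targets and for the synthetases, 0.15 for glycolysis, 0.2 for the proteasome and 0.46 for mitochondrial respiration.

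Of 29 type I interferon response genes, 22 rose, 7 did not pass and 27 rose when adjusted over the list alone (relative median 2.14, camera adjusted p = 7.1e-98, and camera adjusted p = 0.018 with an estimated correlation). Mx2, an antiviral GTPase, rose 10.3-fold (log2 3.36 ± 0.41 SE, edgeR adjusted p = 4.7e-13). Summed CPM of 10 haematopoietic markers moved with this group, at 7.76 ± 0.89 in siControl LacZ, 13.8 ± 1.3 in siHsf1 LacZ, 6.17 ± 0.66 in siControl GCN5 and 5.97 ± 0.6 in siHsf1 GCN5 libraries (SD, n = 3), of which Csf1r and Cd68 were tested. Cd68 alone averaged 6.83 CPM over all libraries, so the sum rests mostly on this gene. Of 20 actin and SRF target genes 2 rose (2 when adjusted over the list alone; relative median 0.42, camera adjusted p = 7.5e-05). These were Myl9, a myosin light chain, 4.59-fold, and Acta2, smooth muscle actin, 3.13-fold. Of 19 immediate early genes, 1 rose and 1 fell (1 and 1 when adjusted over the list alone; relative median 0.40, camera adjusted p = 0.0032), the riser being Dusp1, a MAP kinase phosphatase, and the other Myc. NF-kB targets (21 genes, relative median 0.45, camera adjusted p = 0.00011), autophagy and lysosome genes (27 genes, 0.42, camera adjusted p = 0.00037) and extracellular matrix genes (28 genes, 0.28, camera adjusted p = 0.0015) passed with 0 members called by spike-in scaling. With an estimated correlation these last 5 lists had a camera adjusted p = 0.73, and with TMM scaling too 0.011 for actin and NF-kB targets, 0.025 for autophagy, 0.049 for immediate early and 0.098 for matrix genes. With TMM scaling edgeR called 16, 19 and 17 members of the last 3 lists higher, such as Tnfaip3, an inhibitor of NF-kB (1.11 ± 0.08 SE), Gla, a lysosomal enzyme (1.05 ± 0.10 SE), and Thbs1 (1.01 ± 0.10 SE). The median of the matrix list itself was -0.08 with spike-in and 0.31 with TMM scaling. The 6 lists that did not pass were the MYC network (camera adjusted p = 0.17), SAGA and ATAC subunits (0.77), DNA replication (0.31), the unfolded protein response (0.52), ATF4 targets (0.69) and histones (0.95).

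With spike-in scaling edgeR called 856 of 12187 genes, 121 higher and 735 lower (2700 at an unadjusted p under 0.05). With TMM it called 4944, 2571 higher and 2373 lower, and 829 genes were called by both in the same direction. The 6 LacZ libraries fitted alone with spike-in scaling gave 129 genes, 57 higher and 72 lower. Without siControl LacZ replicates 1, 2 and 3 the count was 230, 1488 and 363, and without siHsf1 LacZ replicates 1, 2 and 3 it was 3337, 319 and 167. The split was near even without siControl LacZ replicate 1 (110 higher, 120 lower), siHsf1 LacZ replicate 2 (148 and 171) and siHsf1 LacZ replicate 3 (72 and 95).

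**Figure D2:**
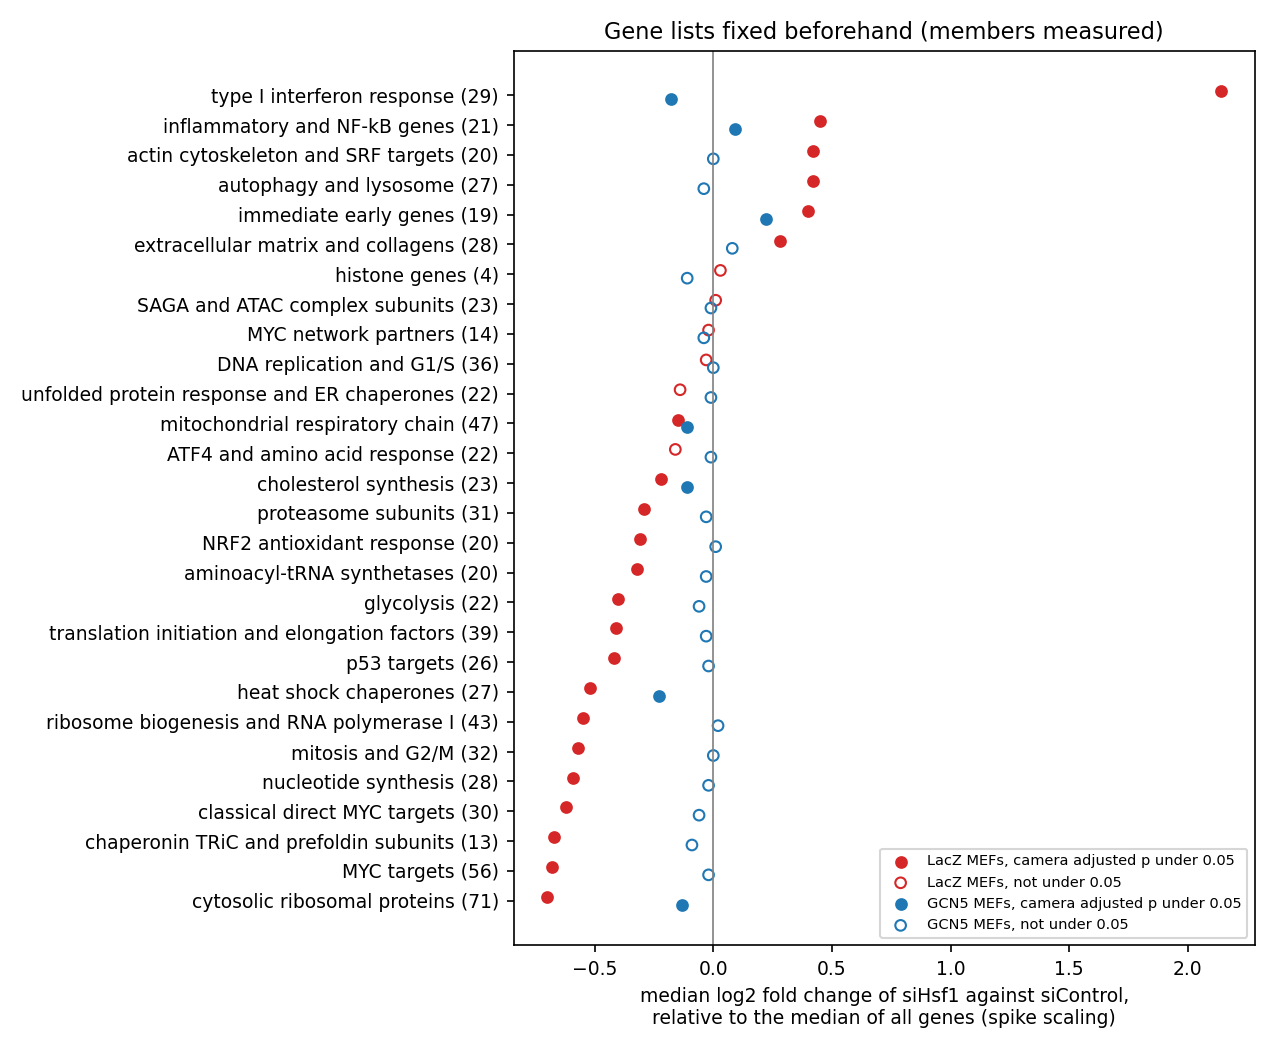
Median log2 fold change of siHsf1 against siControl of 28 gene lists relative to all genes (x axis, spike-in scaling; members measured beside each name), in LacZ (red) and GCN5 MEFs (blue). Filled points passed camera at an adjusted p under 0.05 and open points did not; the interferon list lies at 2.14 in LacZ and -0.18 in GCN5 MEFs, and the median of the matrix list before subtraction turns from -0.08 to 0.31 with TMM in LacZ MEFs.

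Knockdown of Hsf1 in the GCN5 line, which asks what loss of HSF1 does where GCN5 is added, gave few calls, and the fixed list of 27 heat-shock chaperones was lower relative to all genes by camera with its preset correlation (relative median -0.23, camera adjusted p = 2.6e-06). When the correlation was estimated, its camera adjusted p was 0.99, and 0.076 with TMM scaling too, and 21 of the 27 members were not called with TMM. With TMM scaling Hsf1 fell to 0.544-fold (log2 fold change -0.88 ± 0.08 SE, n = 3 per group, edgeR adjusted p = 8.2e-07), while with spike-in scaling it had -0.93 ± 0.32 (SE, edgeR adjusted p = 1). Kat2a had -0.04 ± 0.32 (SE, edgeR adjusted p = 1) and Myc 0.23 ± 0.32 (SE, edgeR adjusted p = 1) with spike-in scaling. Hsph1, an HSP110 exchange factor, fell with TMM scaling (log2 -0.40 ± 0.06 SE, edgeR adjusted p = 0.0008), as did Dnajb1, an HSP40 co-chaperone (-0.50 ± 0.09 SE, edgeR adjusted p = 0.0084). The other TMM calls among chaperones, chosen after their values were seen, were Ahsa1, Fkbp4, Hsp90aa1 and Hsp90ab1, all lower.

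Of 27 chaperones, 1, Hspa4l, fell with spike-in scaling (1 when adjusted over the list alone), and 6 with TMM (16 when adjusted over the list alone). Hspb1 had log2 -0.59 ± 0.33 (SE, edgeR adjusted p = 1). Mitochondrial respiration (relative median -0.11, camera adjusted p = 8.7e-05), ribosomal protein (-0.13, camera adjusted p = 0.042), cholesterol synthesis (-0.11, camera adjusted p = 0.042) and interferon genes (-0.18, camera adjusted p = 0.013) also passed as lower. NF-kB targets (0.09, camera adjusted p = 0.04) and immediate early genes (0.22, camera adjusted p = 0.013) passed as higher. With an estimated correlation each of the 7 lists had a camera adjusted p = 0.99, and none passed with TMM scaling and an estimated correlation (0.076 to 0.65). Ptgs2, the inducible cyclooxygenase, rose with TMM scaling (log2 0.69 ± 0.08 SE, edgeR adjusted p = 2e-05), and Egr1, an immediate early transcription factor, had 0.54 ± 0.11 (SE, edgeR adjusted p = 0.093). MYC V2 targets (median -0.04, camera adjusted p = 0.96) and classical MYC targets (-0.08, camera adjusted p = 0.83) did not pass.

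With spike-in scaling edgeR called 5 genes (111 at an unadjusted p under 0.05), chosen here after their values were seen: Usp39, Slc25a1, Phtf1 and Gabarap higher and Hspa4l, an HSP110-family chaperone, lower. TMM called none of these 5 and called 20 others, 8 higher and 12 lower. The TMM count was 84 without a filter (45 higher, 39 lower) and 262 with the 2 groups fitted alone (133 higher, 129 lower). Without siControl GCN5 replicate 2 the spike-in split was 2 higher and 5 lower, and without siControl GCN5 replicate 1 it was 3 and 3. Phtf1 (2.01 ± 0.44 SE) and Hspa4l (-2.94 ± 0.47 SE) met the rule for named genes, and Gabarap had an SD of 31.9 CPM on a mean of 29.2 in siHsf1 libraries. Without siHsf1 GCN5 replicates 1 and 3 the spike-in count was 8 and 9. The TMM count was 7, 5 and 6 without siControl GCN5 replicates 1, 2 and 3, and 12, 11 and 4 without siHsf1 GCN5 replicates 1, 2 and 3. The 7 passing lists became 4, 2 and 4 without siControl GCN5 replicates 1, 2 and 3, and 4, 4 and 2 without siHsf1 GCN5 replicates 1, 2 and 3.

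Under siControl, cholesterol synthesis genes were higher and interferon genes lower in the GCN5 than in the LacZ line, relative to all genes, by camera with its preset correlation, with 0 of 23 and 4 of 29 members called by edgeR with spike-in scaling. Under an estimated correlation the camera adjusted p was 0.97 for both lists, and with TMM scaling too 0.0013 and 0.26. The comparison asks what GCN5 expression does with HSF1 present, and line and depth coincide in it. Hoxb9, a posterior patterning factor (chromosome 11, 96271330 to 96276595), was 8.58-fold higher, from 3.28 ± 1.41 to 27.4 ± 3.03 spike-scaled CPM (SD, n = 3 per group; log2 3.10 ± 0.38 SE, edgeR adjusted p = 6.8e-12). Srsf1, a splicing factor, was 5.55-fold higher (log2 2.47 ± 0.34 SE, edgeR adjusted p = 8.3e-10). Saa3, an acute-phase protein (chromosome 7, 46711998 to 46715676), was lower, at 0.141-fold (log2 -2.83 ± 0.43 SE, edgeR adjusted p = 4.8e-08). Kat2a had log2 -0.20 ± 0.32 (SE, edgeR adjusted p = 0.64) with spike-in and 0.19 ± 0.06 (SE, edgeR adjusted p = 0.051) with TMM scaling.

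The other named higher genes, in log2 fold change (± SE), were Hnrnph3 (2.06 ± 0.35) and Rbmx (1.59 ± 0.33), both RNA-binding splicing proteins, Hoxd10 (1.86 ± 0.35), Hoxa5 (1.64 ± 0.35), Slco1a5, an organic anion transporter (1.83 ± 0.45), Camta1 (1.60 ± 0.35) and Mmp9, a gelatinase (1.56 ± 0.36). Rps27rt (1.68 ± 0.33) is a near-copy of another ribosomal gene. The other named lower genes were Sned1 (-2.70 ± 0.40), Capn6 (-2.43 ± 0.44), Ly6c1 (-2.24 ± 0.34), Eno3, a muscle enolase (-2.19 ± 0.41), Als2cl (-2.12 ± 0.36), Lcn2, an iron-sequestering acute-phase protein (-1.92 ± 0.33), and the interferon-induced Oas3 (-2.18 ± 0.45), Oas1a (-2.05 ± 0.44) and Nlrc5 (-2.07 ± 0.38).

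Of 23 cholesterol synthesis genes, 0 were called with spike-in scaling (0 when adjusted over the list alone) and 18 were higher with TMM (19 when adjusted over the list alone). The relative median was 0.63 (camera adjusted p = 2.1e-09, 0.97 with an estimated correlation, and 0.0013 with TMM and an estimated correlation). With TMM, Cyp51 had log2 0.94 ± 0.09 (SE) and Idi1 1.09 ± 0.19 (SE), both enzymes of sterol synthesis. Of 29 interferon genes, 4 (Oas3, Oas1a, Usp18 and Rsad2) were lower (15 when adjusted over the list alone; relative median -0.36, camera adjusted p = 4.6e-06, and 0.97 with an estimated correlation), with summed haematopoietic markers at 7.76 CPM in the LacZ and 6.17 CPM in the GCN5 line. Of 28 extracellular matrix genes, 2 were higher and 1 lower (5 and 7 when adjusted over the list alone; camera adjusted p = 0.0024, and 0.97 with an estimated correlation). They were Postn, periostin (3.56 ± 0.69 SE), and Col3a1 (1.32 ± 0.34 SE), higher, and Col6a3 (-1.92 ± 0.34 SE), lower. The median of the matrix list was -0.20 with spike-in and 0.18 with TMM scaling, and 0.18 relative to all genes. With TMM and an estimated correlation the matrix list had a camera adjusted p = 0.76. MYC V2 targets (relative median -0.06, camera adjusted p = 0.57) and NF-kB targets (2 of 21 lower, camera adjusted p = 0.16) did not pass.

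With spike-in scaling edgeR called 183 genes, 66 higher and 117 lower (1424 at an unadjusted p under 0.05). With TMM it called 1171, 665 higher and 506 lower, and 170 by both. Without siControl LacZ replicates 1 and 2 the spike-in count was 110 and 291, and without siControl GCN5 replicates 2 and 3 it was 104 and 120. The split turned to 66 higher and 44 lower without siControl LacZ replicate 1, and to 63 and 41 without siControl GCN5 replicate 2.

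Under siHsf1, interferon genes were lower in the GCN5 than in the LacZ line, with 28 of 29 called. By camera with its preset correlation MYC target and ribosome biogenesis lists were higher and autophagy and lysosome genes lower relative to all genes, with 3 of 56 MYC V2 targets, 4 of 43 ribosome biogenesis genes and 6 of 27 autophagy genes called. With an estimated correlation the camera adjusted p was 0.014 for the interferon list and 0.87 for the others. With TMM scaling too it was under 0.05 for the MYC target, ribosome biogenesis and autophagy lists. The comparison asks what GCN5 expression does with HSF1 reduced. Usp18 (chromosome 6, 121245906 to 121270917) was lower, at 0.0345-fold (log2 -4.86 ± 0.40 SE, n = 3 per group, edgeR adjusted p = 1.3e-29), and Ifit3 too (-4.63 ± 0.40 SE, edgeR adjusted p = 1.1e-27). Hoxb9 was 12-fold higher (3.59 ± 0.39 SE, edgeR adjusted p = 1.9e-17). Hspd1 was higher (1.21 ± 0.32 SE, edgeR adjusted p = 0.0054), and with TMM Kat2a (1.00 ± 0.06 SE, edgeR adjusted p = 3.5e-12), Myc (0.67 ± 0.08 SE, edgeR adjusted p = 1.9e-07) and Hsf1 (0.42 ± 0.08 SE, edgeR adjusted p = 0.00019) were higher. With spike-in scaling these 3 had an edgeR adjusted p of 0.067, 0.38 and 0.71.

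The other named lower genes, in log2 fold change (± SE), were Oas1a (-4.63 ± 0.44), Oas3 (-4.52 ± 0.43), Saa3 (-4.42 ± 0.45), Xaf1 (-4.40 ± 0.39), Ifi44 (-4.03 ± 0.38), Irf7 (-3.86 ± 0.36), Trim30a (-3.82 ± 0.40) and Nlrc5 (-3.38 ± 0.38). The other named higher genes were Acsbg1, an acyl-CoA synthetase (3.58 ± 0.43), Srsf1 (2.86 ± 0.35), Hnrnph3 (2.69 ± 0.36), Krt13, a keratin (2.16 ± 0.35), Rbmx (2.00 ± 0.33) and Mmp9 (1.95 ± 0.35). Spag7 (4.18 ± 0.94) and Gabarap (2.24 ± 0.36) had uneven libraries.

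Of 29 interferon genes, 28 were lower (28 when adjusted over the list alone; relative median -2.71, camera adjusted p = 9.5e-107, and 0.014 with an estimated correlation), and the summed haematopoietic markers stood at 13.8 CPM in siHsf1 LacZ and 5.97 CPM in siHsf1 GCN5 libraries. Of 56 MYC V2 targets, 3 were higher (3 when adjusted over the list alone; relative median 0.57, camera adjusted p = 2.2e-08), with Rcl1 at 1.05 and Mybbp1a at 0.96. Of 30 classical MYC targets, 3 were higher (3 when adjusted over the list alone; 0.47, camera adjusted p = 0.00011), namely Cad (1.16), Pno1 (1.14) and Ncl (1.09). Ribosome biogenesis (4 of 43 higher, 0.57, camera adjusted p = 2.5e-06), nucleotide synthesis (3 of 28 higher, 0.51, camera adjusted p = 4e-05), cholesterol synthesis (5 of 23 higher, 0.71, camera adjusted p = 8e-07) and NRF2 targets (2 of 20 higher, 0.30, camera adjusted p = 0.011) passed as higher. So did chaperones (1 of 27 higher, 0.26, camera adjusted p = 0.029). Ribosomal proteins (0.45, camera adjusted p = 7.9e-07), translation factors (0.42, camera adjusted p = 3.8e-05), mitosis genes (0.58, camera adjusted p = 2.4e-05), TRiC and prefoldin (0.56, camera adjusted p = 0.014) and proteasome subunits (0.32, camera adjusted p = 0.0012) passed with 0 members called by spike-in scaling. With TMM edgeR called 60, 27, 29, 10 and 21 of their members higher. Autophagy and lysosome genes had 6 of 27 lower (11 when adjusted over the list alone; -0.59, camera adjusted p = 8.9e-05), such as Hexa (-1.40) and Gla (-1.40), both lysosomal hydrolases. NF-kB targets had 5 of 21 lower (8 when adjusted over the list alone; -0.26, camera adjusted p = 0.00094), among them Tnfaip3 (-1.39) and Lcn2 (-2.23), and actin and SRF targets 4 of 20 (6 when adjusted over the list alone; -0.35, camera adjusted p = 0.0047), among them Myl9 (-1.80). Apart from interferon these 15 lists had a camera adjusted p of 0.87 with an estimated correlation, or 0.98 for chaperones. With TMM and an estimated correlation it was 0.023 for MYC V2 targets, mitosis and autophagy, 0.014 for classical MYC targets, nucleotide and cholesterol synthesis, 0.027 for ribosome biogenesis and 0.021 for actin and SRF targets. The others did not pass there, at 0.23 for ribosomal proteins and the proteasome, 0.21 for TRiC and prefoldin, 0.12 for chaperones and 0.089 for translation factors, NRF2 and NF-kB targets.

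With spike-in scaling edgeR called 663 genes, 222 higher and 441 lower (1792 at an unadjusted p under 0.05). With TMM it called 5464, 2711 higher and 2753 lower, and 646 by both. Without siHsf1 GCN5 replicates 1, 2 and 3 the spike-in count was 369, 386 and 391, and without siHsf1 LacZ replicate 3 it was 372. The split turned to 501 higher and 273 lower without siHsf1 LacZ replicate 1, and was 127 and 818 without siHsf1 LacZ replicate 2. Rn18s, the 18S ribosomal RNA, took 4.42% ± 0.72 of counts in siHsf1 LacZ and 3.32% ± 0.06 in siHsf1 GCN5 libraries (SD, n = 3), and each siHsf1 GCN5 library lay below each other library.

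The interaction, which tests whether the siHsf1 effect differed between the lines, was negative for interferon genes, with 12 of 29 called, and, by camera with its preset correlation, positive relative to all genes for lists of MYC targets, ribosome biogenesis and mitosis, with 0 members called by edgeR with spike-in scaling. When the correlation was estimated, the camera adjusted p was 0.023 for the interferon list and 0.97 for each of the others. With TMM scaling too it was under 0.05 for the MYC target, ribosome biogenesis and mitosis lists. For Ifit3 the log2 effect of siHsf1 was lower in the GCN5 than in the LacZ line by a difference of -4.04 ± 0.55 (SE, n = 3 per group, edgeR adjusted p = 2e-09). For Reep6 the difference was 2.80 ± 0.58 (SE, edgeR adjusted p = 0.00085). With TMM scaling it was 1.23 ± 0.08 (SE, edgeR adjusted p = 6.3e-11) for Hspd1, 1.14 ± 0.07 (SE, edgeR adjusted p = 6.3e-11) for Ncl, 0.81 ± 0.09 (SE, edgeR adjusted p = 2.3e-07) for Kat2a and 0.88 ± 0.11 (SE, edgeR adjusted p = 2.4e-06) for Myc. For Hsf1 it was 0.41 ± 0.11 (SE, edgeR adjusted p = 0.011), and with spike-in scaling Kat2a, Myc and Hsf1 had an edgeR adjusted p of 0.45, 0.39 and 0.76.

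The other named positive differences, in log2 (± SE), were Eda2r (2.43 ± 0.50), Ppl (2.34 ± 0.58), Acsbg1 (2.23 ± 0.57), C1qbp, a mitochondrial matrix protein (1.86 ± 0.46), Prrg4 (1.82 ± 0.48), Lrp8, a lipoprotein receptor (1.75 ± 0.46), and Pofut2 (1.70 ± 0.46), with Trim37 and Srp54b (both 2.23) on uneven libraries. The other named negative ones were Ifi44 (-3.60 ± 0.51), Usp18 (-3.26 ± 0.56), Xaf1 (-3.21 ± 0.52), Irf7 (-2.72 ± 0.48), Mmp13 (-2.66 ± 0.53), Oas1a (-2.58 ± 0.65), Sp100 (-2.49 ± 0.56) and Gbp3, an interferon-induced GTPase (-2.46 ± 0.47). Rad9a (-2.88 ± 0.66), Trim37 and Srp54b had a TMM edgeR adjusted p of 0.073, 0.33 and 0.15.

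Of 29 interferon genes, 12 had a negative difference (24 when adjusted over the list alone; relative median -2.28, camera adjusted p = 1.2e-91, and 0.023 with an estimated correlation), while the summed haematopoietic markers went from 7.76 to 13.8 CPM under siHsf1 in the LacZ line and from 6.17 to 5.97 CPM in the GCN5 line. MYC V2 targets (relative median 0.61, camera adjusted p = 2e-13), classical MYC targets (0.58, camera adjusted p = 5.8e-07), ribosomal proteins (0.55, camera adjusted p = 2.3e-12), ribosome biogenesis (0.58, camera adjusted p = 9e-09), nucleotide synthesis (0.57, camera adjusted p = 5.8e-07) and mitosis genes (0.55, camera adjusted p = 2.7e-07) passed as positive. Their members called were 0 with spike-in scaling and 38 of 56, 21 of 30, 58 of 71, 29 of 43, 23 of 28 and 29 of 32 with TMM, all positive. Translation factors (0.37, camera adjusted p = 6.3e-05), chaperones (0.34, camera adjusted p = 0.028), TRiC and prefoldin (0.55, camera adjusted p = 0.0044), p53 targets (0.31, camera adjusted p = 0.0016), NRF2 targets (0.30, camera adjusted p = 0.016) and proteasome subunits (0.26, camera adjusted p = 0.0031) also passed as positive. Autophagy and lysosome genes (-0.46, camera adjusted p = 0.00025) and actin and SRF targets (-0.41, camera adjusted p = 0.00027), with Myl9 (-2.34 ± 0.54 SE) and Acta2 (-1.92 ± 0.47 SE), passed as negative relative to all genes. So did NF-kB targets (-0.17, camera adjusted p = 0.038) and matrix genes (-0.28, camera adjusted p = 0.038), whose own medians were 0.17 and 0.06 with spike-in and -0.19 and -0.30 with TMM scaling. With an estimated correlation each of the 16 lists other than interferon had a camera adjusted p = 0.97. With TMM and an estimated correlation the camera adjusted p was 0.012 for MYC V2, 0.0058 for classical MYC targets, 0.013 for ribosome biogenesis, 0.0058 for nucleotide synthesis, 0.014 for mitosis, 0.012 for p53 targets, 0.015 for autophagy, 0.01 for actin and SRF targets and 0.047 for NF-kB targets. The others did not pass there, at 0.17 for ribosomal proteins, 0.16 for TRiC and prefoldin, 0.079 for chaperones, 0.056 for translation factors, 0.072 for NRF2 targets, 0.29 for the proteasome and 0.22 for matrix genes.

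Across the 4944 genes that TMM called in the LacZ line, 59.9% had the same sign in the GCN5 line, with a median absolute log2 fold change of 0.458 in LacZ and 0.1 in GCN5 MEFs. Across all 12187 genes the fold changes of the lines, which share no libraries, correlated at r = 0.055 (rho = 0.125), across genes that are not independent replicates. With spike-in scaling edgeR called 48 genes in the interaction, 21 positive and 27 negative (924 at an unadjusted p under 0.05), and with TMM 2677, 1341 positive and 1336 negative, of which 39 by both. Without siHsf1 LacZ replicate 1 the spike-in count was 268, and without siControl LacZ replicate 2 and siHsf1 LacZ replicate 2 it was 75 and 76. The split turned to 237 positive and 31 negative without siHsf1 LacZ replicate 1, to 53 and 22 without siControl LacZ replicate 2, to 25 and 22 without siControl GCN5 replicate 1 and to 18 and 17 without siHsf1 GCN5 replicate 3.

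**Figure D3:**
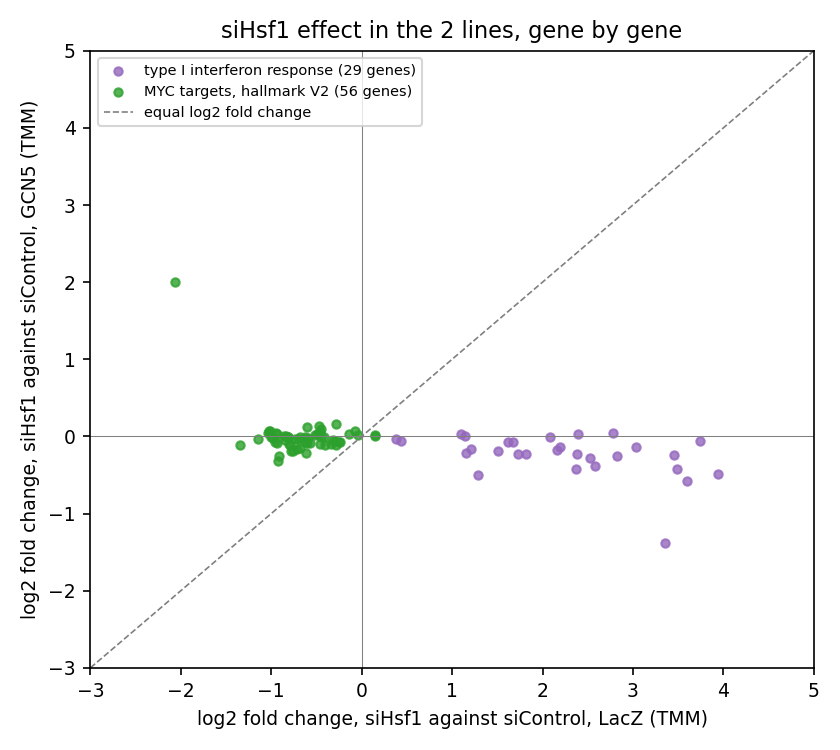
Log2 fold change of siHsf1 against siControl with TMM scaling in LacZ (x axis) and GCN5 MEFs (y axis), with a point per gene, 29 interferon genes in purple, 56 MYC V2 targets in green and a dashed line of equal fold change. Across all 12187 genes r is 0.055.

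The c-MYC peaks compare occupancy between Hsf1 WT and Hsf1 CKO MEFs on mm10. The WT list holds 220037 peaks over 510 Mb (median width 1835 bp) and the CKO list 6386 peaks over 11.5 Mb (median width 1658 bp), a ratio of 34.5. Of the CKO peaks 5960, or 93.3% (Wilson 95% interval 92.7% to 93.9%), overlapped a WT peak, against 49.6% to 53% after shifting. The maximal signals were whole multiples, to within 0.01 of a step, of 0.000684 in WT and 0.000361 in CKO, so that each list carries 1 scale factor, with a ratio of 1.9. The mean signal per bp was 0.00204 in WT and 0.00166 in CKO peaks as deposited, and 2.98 and 4.6 in steps, the opposite order. At shared peaks the median WT to CKO ratio of maximal signal was 1.9 as deposited and 1 in steps. The median peak maximum was 6 steps in WT and 10 in CKO. Among the 19 autosomes, WT peaks were densest on chromosomes 15 (173 per Mb) and 8 (148 per Mb) and sparsest on chromosome 12 (18.9 per Mb). CKO peaks reached 6.83 per Mb on chromosome 11 and 6.61 per Mb on chromosome 15. Of WT peaks 3.98% lay near the start of a tested gene, against 57.6% of CKO peaks. This share rose with the height of the peak in both lists. For maxima of 5 to 6 steps it was 1.53% in WT and 29.5% in CKO. For 13 to 24 steps it was 47.1% and 71.1%, and for 25 steps or more 67.3% and 78.6%.

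WT peaks lay within 1000 bp of the starts of most tested genes, and CKO peaks within 1000 bp of most starts of MYC V2 targets and ribosomal protein genes but of few starts of interferon genes. Of 12153 tested genes with a start, 9397 or 77.3% (Wilson 95% interval 76.6% to 78.1%) had a WT peak, against 43.7% to 44.8% after shifting. A CKO peak lay at 4274 or 35.2% (34.3% to 36%), against 2.58% to 3.34% after shifting. Both lists had a peak at 4151 starts, WT alone at 5246, CKO alone at 123 and neither at 2633. Genes that were not tested for expression had a WT peak at 40.1% and a CKO peak at 4.05% of starts. Among MYC V2 targets 56 of 56 had a WT and 47 of 56 a CKO peak (83.9%, Wilson 95% interval 72.2% to 91.3%). Among classical MYC targets the numbers were 28 and 21 of 30, among chaperones 24 and 17 of 27, among ribosomal proteins 66 and 54 of 71, among ribosome biogenesis genes 41 and 32 of 43, and among SAGA and ATAC subunits 20 and 17 of 23. Interferon genes had a WT peak at 21 and a CKO peak at 4 of 29 starts (13.8%, Wilson 95% interval 5.5% to 30.6%), p53 targets at 19 and 5 of 26, and matrix genes at 20 and 6 of 28.

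At the Ncl start the WT peak (chromosome 1, 86356700 to 86364352) had a signal of 33.5 and a maximum of 37 steps, and the CKO peak (86358018 to 86360621) a signal of 13.5 and a maximum of 52 steps. The Cad start reached 20 steps in WT and 11 in CKO, and Nme1, a nucleoside diphosphate kinase, 27 and 52. At the 21 classical MYC targets with a peak in both lists the median ratio of WT to CKO maximum was 1.85 as deposited and 0.97 in steps, and at 17 chaperones it was 1.9 and 1. Summed signals are scaled and grow with the width of a peak, so maxima in steps stand beside them here. Myc itself had a signal of 24.9 in WT (chromosome 15, 61983582 to 61992841) and 2.09 in CKO, with maxima of 10 and 9 steps, and Kat2a 40.2 in WT (chromosome 11, 100700999 to 100715758) and 3.2 in CKO, with 20 and 15 steps. Hsf1 and Bop1, a ribosome biogenesis gene, share a start region whose peak had a signal of 18.9 in WT and 5.72 in CKO, with 21 and 24 steps. Hspd1 and Hspe1, which encode the mitochondrial chaperonin pair, share one with 24.6 in WT and 9.18 in CKO, with 22 and 30 steps. Chaperones with a WT but no CKO peak were Hspa4, Hspa4l, Hspb1, Hspb8, Cryab, Bag3 and Serpinh1. Among classical MYC targets these were Tert, Tfam, Ireb2, Prdx3, Cdc25a, E2f2 and Slc2a1. The highest summed WT start signals lay in broad peaks, at Endou (150 over chromosome 15, 97708272 to 97760989, with a maximum of 12 steps), at Grasp and Nr4a1 (148, 17 steps), at Gm13251 (123 on chromosome 4, 16 steps) and at Eif4b (115, 30 steps). Grasp, Nr4a1 and Eif4b also lie on chromosome 15, which had the densest WT peaks of the autosomes. The highest summed CKO start signals were at Cbx5 and Hnrnpa1 (31.8 over chromosome 15, 103238082 to 103243764, 91 steps, with no WT peak), Nr1d1 (19.6, 52 steps), Tuba1b (17.4, 30 steps, with no WT peak), Cct3 (16.7, 60 steps) and Mnt (16.5, 58 steps), a MYC network repressor. In WT the Cct3 start reached 71 and the Mnt start 54 steps.

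**Figure D4:**
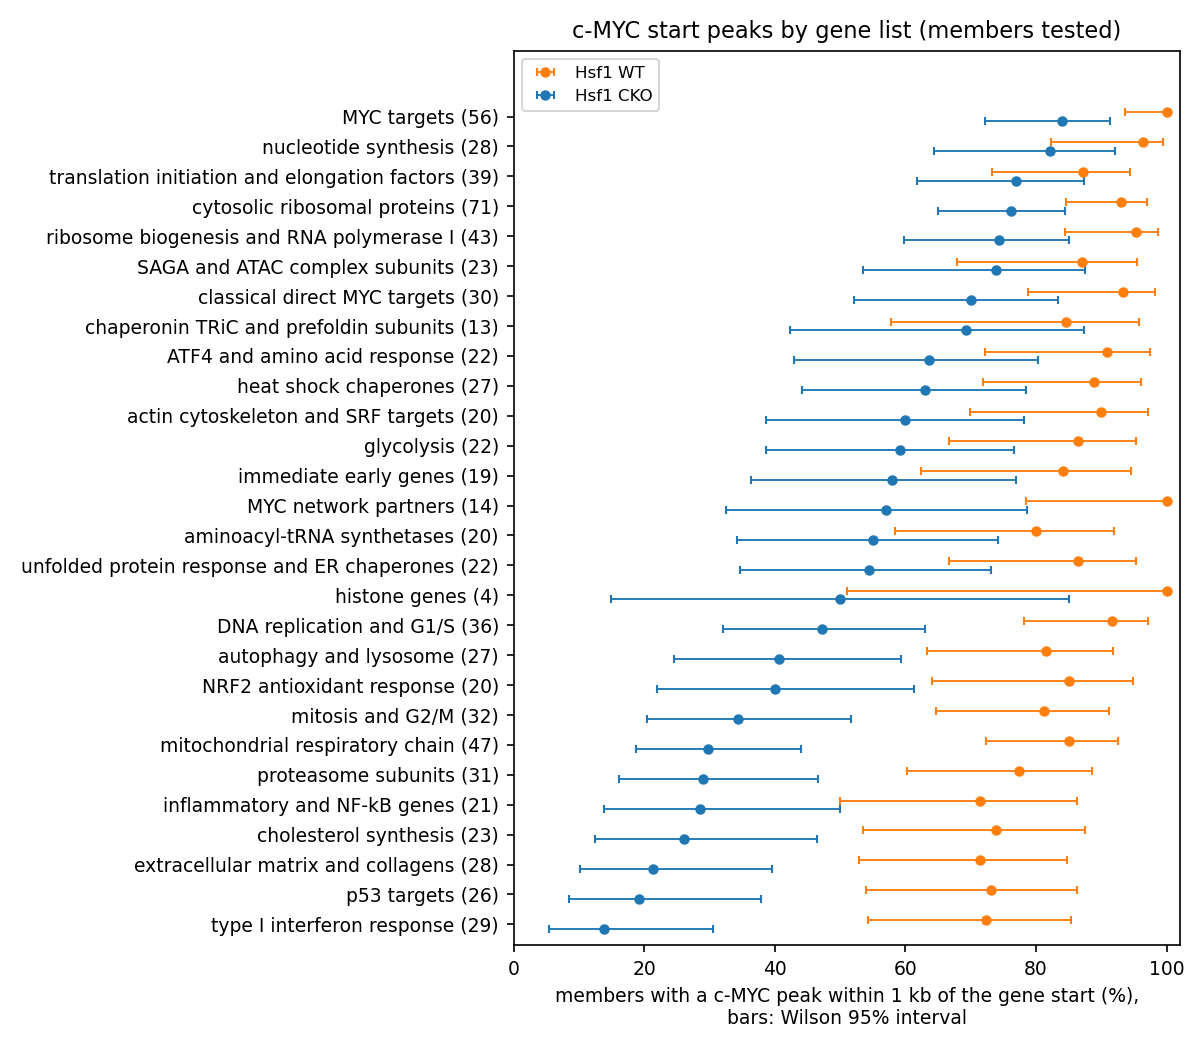
Share (%) of tested members of each gene list with a c-MYC peak within 1000 bp of the gene start in Hsf1 WT (orange) and Hsf1 CKO MEFs (blue), with Wilson 95% intervals as bars. MYC V2 targets have 83.9% and interferon genes 13.8% in CKO.

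Genes bound by c-MYC were compared with siHsf1 effects to ask whether expression changes follow occupancy. In the LacZ line the 1000 genes with the highest summed WT start signals had a median log2 fold change of -0.38, the 5246 genes bound in WT alone -0.33 and the 4151 bound in both -0.42, against -0.36 for all genes. The summed signal covers each whole peak that reaches the start window and grows with its width. This ranking therefore does not pick the starts with the highest maxima. No set passed, with a camera adjusted p of 0.91, 0.73 and 0.19, and 0.99 with an estimated correlation. With TMM scaling and the preset correlation no set passed either, at a camera adjusted p of 0.9, 0.3 and 0.093. With TMM scaling and an estimated correlation the set bound in both passed as lower (median -0.04, camera adjusted p = 0.0024). The set bound in WT alone passed as higher (0.05, camera adjusted p = 0.006), against a median of 0.02 for all genes. For the sets bound in both and in WT alone the estimated correlation was thus the less strict choice with TMM scaling. These 2 sets share no gene and together hold the 9397 of 12153 tested genes with a WT peak. Their 2 results are therefore not independent. Of the genes bound in both, edgeR with TMM called 28.3% lower and 18.9% higher, and of those bound in WT alone 15.2% lower and 23.3% higher. The sets also differed in peak height. The median WT maximum was 8 steps at starts bound in WT alone and 12 at those bound in both. After shifting, 43.7% to 44.8% of starts had a WT peak. The lowest total signal listed was 3451 steps in WT and 4324 in CKO. Binding in WT alone therefore does not show binding lost in CKO. Peaks and RNA come from different MEF lines with different ways of reducing HSF1. With the preset correlation and either scaling 0 of 3 sets passed camera in the other comparisons too. With TMM and an estimated correlation 2 of 3 passed for the line under siHsf1, the set bound in WT alone as lower and the set bound in both as higher (camera adjusted p = 0.0068 for each). So did the same 2 in the interaction (0.0083 and 0.0029), and 0 of 3 for siHsf1 in GCN5 and for the line under siControl.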

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

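The test of depth and the splits of the libraries were set before their results were seen; the tests of proportional knockdown, of haematopoietic cells, of a response in either line, of a single library, of the scale factor and of regional background, and the look at which splits called many genes, were chosen after. The gene and list values of the next paragraph are differences of the siHsf1 effect between the lines, GCN5 minus LacZ, by a test of the interaction; groups of 3 libraries are too small to test for a library far from the others.

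The interaction called 48 genes with spike-in and 2677 with TMM scaling. With TMM the difference was 0.41 for Hsf1, 0.81 for Kat2a and 0.88 for Myc. Positive differences of single genes, in log2 with spike-in scaling, were Reep6 2.80, Eda2r 2.43, Ppl 2.34, Trim37 2.23, Srp54b 2.23, Acsbg1 2.23, C1qbp 1.86, Prrg4 1.82, Lrp8 1.75 and Pofut2 1.70. Negative ones were Ifit3 -4.04, Ifi44 -3.60, Usp18 -3.26, Xaf1 -3.21, Rad9a -2.88, Irf7 -2.72, Mmp13 -2.66, Oas1a -2.58, Sp100 -2.49 and Gbp3 -2.46. Gene lists with positive relative medians were MYC V2 targets (0.61), classical MYC targets (0.58), ribosome biogenesis (0.58), nucleotide synthesis (0.57), ribosomal proteins (0.55), TRiC and prefoldin (0.55), mitosis (0.55), translation factors (0.37), chaperones (0.34), p53 targets (0.31), NRF2 targets (0.30) and proteasome subunits (0.26). Lists with negative ones were interferon genes (-2.28), autophagy and lysosome genes (-0.46), actin and SRF targets (-0.41), matrix genes (-0.28) and NF-kB targets (-0.17), of which the last 2 had positive medians of their own with spike-in scaling (0.06 and 0.17). These calls come from camera with its preset correlation. With an estimated correlation 1 of the 28 lists passed, interferon genes (camera adjusted p = 0.023), and each of the other 16 had a camera adjusted p = 0.97. With spike-in scaling this estimate holds the error shared by all genes of a library, so 0.97 does not show that a list is unchanged. With TMM and an estimated correlation both MYC lists, ribosome biogenesis, nucleotide synthesis, mitosis, p53, autophagy, actin and NF-kB lists also passed. Ribosomal proteins, TRiC and prefoldin, chaperones, translation factors, NRF2 targets, the proteasome and matrix genes did not pass there.

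Knockdown of Hsf1 called 4944 genes in the LacZ line and 20 in the GCN5 line with TMM scaling. Lower depth of the GCN5 libraries is argued against, since LacZ counts thinned to 3.93 M counts still gave at least 4274 called genes in 5 draws. A weaker knockdown with effects in proportion to it is argued against too, since the highest slope of GCN5 on LacZ log2 fold changes was 0.055 over fits without 1 library, far below a ratio of Hsf1 log2 fold changes of 0.684 (0.65 to 0.723). A threshold in the response to HSF1 level, a batch that coincides with the lines, and GCN5 expression itself, which the design names, remain open and untested.

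Interferon genes were 4.57-fold as high at the median under siHsf1 in the LacZ line with TMM scaling. With spike-in scaling the list had an interaction (relative median -2.28). A response to the siRNA in either line alike is argued against by the GCN5 line. There the highest median without 1 library was -0.14 with TMM scaling, against 2.17 to 2.24 in the LacZ line. A response to the siRNA that depends on the line stays open and untested. A single aberrant library is argued against by a gap of 1.75 (log2, TMM scaling) between the lowest siHsf1 and the highest siControl LacZ library. Haematopoietic cells in the siHsf1 LacZ cultures cannot be told apart. Their summed markers, of which Csf1r and Cd68 passed the filter, were 1.78-fold as high, up to 2.03-fold in 1 pairing. This sum rests mostly on Cd68, with a mean of 6.83 CPM over all libraries. The sum in single LacZ libraries stood at 7.19 to 8.79 CPM with siControl and 12.26 to 14.63 CPM with siHsf1. The markers rose less than the interferon genes, but the bound set against this cause was not met. Reduced HSF1, the difference that the design names, may also act on these genes in a way that depends on the line, which these data do not test further.

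The WT list holds 34.5 times as many c-MYC peaks as the CKO list. The scale factor in the deposited signal is argued against as the whole cause, since the same floor on unscaled signal still left 22.2 times as many WT peaks. Regional background that differs between chromosomes cannot be told apart. Over 19 autosomes the rho of WT peaks per Mb with tested genes per Mb was 0.32 (permutation p = 0.18). This value lay between the bounds set for either outcome. Sequencing depth of the CUT&RUN libraries, the calling threshold and the use of the E. coli spike-in are unknown, and a loss of c-MYC occupancy without HSF1, which the design names, stays open and untested.

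For each comparison of 2 groups the 6 libraries make 10 splits, too few for a share under 0.05. With spike-in scaling the real and highest other counts were 856 and 8331 for siHsf1 in LacZ (2 splits as large), 5 and 9 for siHsf1 in GCN5 (3 splits), 183 and 138 for the line under siControl (1 split), and 663 and 11 for the line under siHsf1 (1 split). With TMM they were 4944 and 2, 20 and 1, 1171 and 60, and 5464 and 1, with 1 split as large in each. The split with 8331 calls with spike-in scaling called 0 genes with TMM, so its calls rest on the spike-in scaling. It sets siControl LacZ replicates 1 and 3 and siHsf1 LacZ replicate 1, with subgroup B shares of 0.143%, 0.192% and 0.179%, against the other libraries, with 0.242%, 0.362% and 0.251%. For the interaction 8 of 60 splits with spike-in and 5 of 60 with TMM called as many genes as the real 48 and 2677, and the highest others were 1932 and 3643, so that by this share alone chance is not excluded. With TMM each of the 4 other splits as large kept the lines apart among siHsf1 libraries, so they hold the line difference under siHsf1 and their counts do not measure chance. The 55 splits that mixed the lines there called at most 2 genes with TMM. These put the line difference, with 5464 TMM calls under siHsf1, into the spread within groups. Their low counts therefore do not measure chance either. With spike-in scaling 4 of the 7 other splits as large kept the lines apart, and 3 of the 55 mixed ones called as many, at most 653.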

How the results depend on the processing

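Scaling on all ERCC transcripts, TMM as a second family of results with its own alternatives, TMM for lists and bound genes, with either correlation, and the floors on peak signal were chosen after the data were seen; the other alternatives were planned. All counts are of genes called by edgeR unless DESeq2 is named, beside the spike-in counts of 856, 5, 183, 663 and 48; DESeq2 used its own size factors, so it changes scaling as well as the tool, and its counts are nearer those with TMM. The cause of each change was not tested, except that a minimum count of 50 tests fewer genes and leaving out a library uses fewer samples. For siHsf1 in LacZ the count was 4944 with TMM, 4931 with RLE, 5042 with total counts, 4237 with DESeq2, 129 with the 2 groups fitted alone and 3661 with a replicate block. It was 167 (without siHsf1 LacZ replicate 3) to 3337 (without siHsf1 LacZ replicate 1) with 1 library left out. For siHsf1 in GCN5 it was 20 with TMM, 19 with RLE, 21 with total counts, 1 with a minimum count of 50, 26 with DESeq2, 3 with the groups alone, 8 with a block and 4 to 9 with 1 library left out. With TMM that count of 20 became 84 without a filter, 262 with the groups alone, 33 with a block and 4 to 12 with 1 library left out. For the line under siControl it was 1171 with TMM, 1172 with RLE, 1136 with total counts, 90 with a minimum of 50, 877 with DESeq2, 1083 with a block and 104 to 291 with 1 library left out. For the line under siHsf1 it was 5464 with TMM, 5463 with RLE, 5381 with total counts, 440 with a minimum of 50, 4633 with DESeq2, 1784 with a block and 369 to 945 with 1 library left out. For the interaction it was 2677 with TMM, 2680 with RLE, 2624 with total counts and 2109 with DESeq2. It was 855 with a block and 35 to 268 with 1 library left out. With the block the split turned to 745 positive and 110 negative. All ERCC transcripts (1095, 4, 196, 743 and 65) and no filter (582, 6, 149, 576 and 42) stayed within 1.5 times. Residuals of equal replicate numbers correlated at r = -0.062 to 0.101 across genes, over 0.1 in 1 of 18 pairs. A correlation across genes cannot see a shift common to all genes of a library. It therefore does not decide whether replicate numbers pair the libraries. The replicate block was planned as an alternative and is not the reported result. As a hint from the data and not from the design, 9 of 12 libraries correlated best with their own number, and the subgroup B share was lowest in replicate 1 of each of the 4 groups. With 1 library left out, the share of TMM calls that were higher was 49.3% to 52% for siHsf1 in LacZ and 49.6% to 53.2% for the line under siHsf1, on either side of even.

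Of 28 lists 22 passed camera for siHsf1 in LacZ, against 1 with an estimated correlation, 8 with fry and 14 with TMM and an estimated correlation. For siHsf1 in GCN5 7 passed, against 0 with an estimated correlation, 0 with fry, 0 with TMM and an estimated correlation, and 2 to 4 with 1 library left out. For the line under siControl 3 passed, against 0 with an estimated correlation, 0 with fry, 7 with RLE, 7 with TMM, 5 with a minimum of 50 and 5 with a block. For the line under siHsf1 16 passed, against 1 with an estimated correlation, 1 with fry and 9 with TMM and an estimated correlation. For the interaction 17 passed, against 1 with an estimated correlation, 1 with fry and 10 with TMM and an estimated correlation. By construction fry compares no list with other genes, and under it the matrix list reversed for the line under siControl (-0.20) and for the interaction (0.058), and NF-kB targets for the interaction (0.17). Of 5369 values of named genes under alternatives, 4354 kept direction and side of the threshold, 318 lost the call, 697 gained one and 0 reversed. Of 1988 list values 1769 kept both, 186 lost the call, 30 gained one and 3 reversed. Of 243 values of the bound gene sets 237 kept both and 6 gained a call, all with TMM and an estimated correlation, where 2 of 3 sets passed for siHsf1 in LacZ, for the line under siHsf1 and for the interaction, against 0 of 3. In counts simulated from means over all groups, edgeR called 76 of 99 2-fold changes with TMM but 38 of 111 with spike-in scaling. These changes were placed in the siHsf1 LacZ libraries. Changes smaller than 2-fold are therefore the more easily missed with spike-in scaling, and the GCN5 line has fewer counts.

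The share of CKO peaks in WT peaks was 94% with the higher-signal peaks of each list, 94.9% with the same floor on scaled signal, 90.7% with the same floor on unscaled signal and 90.5% with an overlap of 50%. The ratio of peak numbers was 69.7 with the scaled and 22.2 with the unscaled floor, and is fixed by construction with the higher-signal peaks. Gene starts with a WT peak were 73.7% within 500 bp, 84.2% within 3000 bp and 66.9% with the higher-signal peaks, and those with a CKO peak 34.1%, 37% and 21.5%. Peak lists have no depth, so no limit of detection is given for them. The E-box search was not run.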

Other observations

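Marker lists of other cell types, fixed with the gene lists, were mostly below the expression filter. Tested members were 2 of 10 haematopoietic markers (1 higher under siHsf1 in LacZ with TMM and 0 called with spike-in scaling), 0 of 9 endothelial, 2 of 10 epithelial (Krt18 and Krt19, 1 lower), 1 of 10 myoblast (Des, 0 called), 2 of 10 adipocyte (1 higher), 3 of 10 chondrocyte and osteoblast (Sox9, Runx2 and Alpl, 2 called of which 1 higher) and 5 of 10 neural markers (2 called, 0 higher). Nes, an intermediate filament of progenitors, reached 432 CPM. In the GCN5 line under siControl, TMM called 1 haematopoietic and 2 epithelial markers lower and 2 chondrocyte and osteoblast and 2 neural markers higher than in the LacZ line.

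The ATF4 list did not pass between the lines under siHsf1 (camera adjusted p = 0.89; 2 of 22 lower with spike-in scaling, and 8 higher and 9 lower with TMM). Its 2 called members, Ddit3 (log2 -1.42, edgeR adjusted p = 0.00079) and Trib3 (-1.30, edgeR adjusted p = 0.0032), both induced in stress responses, were lower in the GCN5 line, and Tnc, tenascin C, was higher (1.57 ± 0.37 SE, edgeR adjusted p = 0.0011, n = 3 per group). Rn18s took 3.92% to 4.77% of counts in siControl LacZ, 3.7% to 5.14% in siHsf1 LacZ, 3.46% to 4.52% in siControl GCN5 and 3.26% to 3.38% in siHsf1 GCN5 libraries. Mitochondrial transcripts took 1.91% to 2.56% in the 12 libraries. Over the 19 autosomes CKO peaks per Mb followed tested genes per Mb (r = 0.68, permutation p = 0.0024, BH 0.0036; rho = 0.68, p = 0.0018; r = 0.45 without the 2 chromosomes farthest from the median). WT peaks per Mb followed CKO peaks per Mb (r = 0.81, permutation p = 2e-05, BH 6e-05; rho = 0.85, p = 4e-05; r = 0.70 without 2). For WT peaks and tested genes r was 0.28 (permutation p = 0.25, BH 0.25) and 0.15 without 2; these 3 relations form 1 family and were examined after the peak numbers were seen.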
